A study of Homo sapiens
Mus musculus with 12 samples.

How the data were processed

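The deposited files are 12 tables of counts per gene and cell barcode from Drop-seq libraries of a mixture of K562 and MEF cells. Per the submitters' processing notes, Picard and featureCounts 1.5.0 were used with the hg19 human and mm9 mouse genomes; the aligner, the rule that chose barcodes and the treatment of molecular identifiers are not given in the sources used here. Each table has 47077 entries, of which 23710 are human genes, 23366 mouse genes and 1 a vector barcode region. The vector region took 0.00708% of all counts and was kept out of totals and tests. The values are whole numbers from 5276 to 1035081 per barcode, and they are taken as read counts, so intervals and floors cover counting error only. Library totals ranged from 4109482 to 6852466 counts over 29 to 125 barcodes.

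Libraries were grouped by cell concentration, PCR cycles and bead share from the labels; replicate numbers follow the order of the samples, and the same number stands for the same cycles and bead share at each concentration. Libraries were matched by these settings. A barcode with at least 500 counts was taken as K562 when at least 90% of its counts fell on human genes, as MEF when at least 90% fell on mouse genes, and as mixed otherwise. The minimum removed 0 barcodes. No doublet caller was run, since mixed barcodes were set apart by species, and pairs of cells of the same species stay undetected. The 33 barcodes holding an undetermined base were kept.

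Measures per library were the mixed share, the number of barcodes, the median counts per cell, the K562 share and the counts of the other species. Cell concentration was tested by an exact two-sided permutation of the concentrations within the matched settings (1296 arrangements, smallest p 0.00154), and PCR cycles and bead share by an exact two-sided permutation of signs over 6 matched pairs (64 patterns, smallest p 0.03125), with Benjamini-Hochberg adjustment over 15 tests. Shares have exact Clopper-Pearson intervals at 95%.

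Counts were summed per library and cell type, giving 24 sums. K562 sums held 3545547 to 5260479 counts and MEF sums 94196 to 1207193. Sums were tested with edgeR 4.0.16 (TMM scaling, low-count filter, quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). K562 was set against MEF over 16005 symbols annotated once per species, with the library as a block, and each setting was tested with the other settings in the model. Gene lists, 20 in number, were tested with camera at its preset correlation (limma 3.58.1), again with an estimated correlation, and with fry. Folds against a cell type without counts are lower bounds from 3 counts over the group, and with 1 to 3 counts a ratio with a 95% counting interval is given. Scores of single cells were computed after thinning to 1000 counts and correlated within libraries, with an exact two-sided sign-flip permutation over library values. The use of libraries with at least 8 cells was decided after the numbers of MEF barcodes were seen, so the MEF correlations rest on 8 libraries rather than 12.

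The named genes are, for K562 against MEF, up to 12 per direction with the largest fold among genes past the threshold, in the same direction in all 12 libraries and with at least 50 CPM, the 4 most abundant measured members of each list, the 10 most abundant genes per cell type, and for each setting up to 10 genes per direction with the smallest adjusted p or, where none passed, the 2 with the smallest p. A sex-linked transcript named by this rule in 2 comparisons is not listed. Some other genes that the rule named are not reported here. Groups, tests, lists, this rule and most alternatives were fixed before the data were examined. Alternatives were DESeq2 1.42.0, median-ratio scaling, no filter, thinned sums, no block, no other settings, other purities (80% and 95%) and minimums, and leaving out each library. Those added after seeing the data were a minimum of 2000 genes or 20000 counts per barcode, no TMM scaling, and leaving out barcodes with an undetermined base, both 1/3-bead libraries at 100 cells per µl, or the 4 libraries at 100 cells per µl.

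The tests of barcode measures, the edgeR tests and the correlations of list scores were tried on simulated data. Camera and fry on the gene lists were not. With 200 changed genes, edgeR recovered 46.3% of log2 changes of 1 and 88.1% of those of 2 for K562 by bead share (11143 genes), 49.3% and 89.6% for K562 by cycles (11160 genes), and 73.1% and 98.5% for K562 by concentration (11177 genes). For MEF it recovered 0% of log2 changes of 1 and 26.9% of those of 2 by cycles (8216 genes), 2.99% and 25.4% by bead share (8190 genes) and 11.9% and 71.6% by concentration (8184 genes). By concentration, a log2 change here is per step to the next higher concentration, so the change from the lowest to the highest is larger. By cycles and bead share it is the whole difference between the levels. The shares by concentration are thus not comparable with those by cycles or bead share. For K562 against MEF the shares were 16.4% and 59.7% (10666 genes). The real comparison called 7168 genes, far more than were changed in the simulation. An adjusted threshold is looser where more genes differ, so these shares do not give the power of the real comparison. A first simulation without covariation gave correlations further from 0 than a limit set for that test. The limit was dropped, and 40 such simulations were run. Averaged over the 40, the mean correlations of the pairs of scores lay between −0.0387 and −0.00136. In single simulations they ranged from −0.264 to 0.265. For globin with heat shock, 7 of the 40 had a sign-flip permutation p under 0.05 before adjustment, the most of any pair. Scripts used R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Gene positions are those of the deposited tables.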

Results

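Single-cell RNA sequencing by Drop-seq, which captures cells in droplets with barcoded beads, was applied to a mixture of K562 cells, a human erythroleukaemia line, and mouse embryonic fibroblasts (MEF). Mixing species lets a barcode that collected RNA from both be seen. The 12 libraries crossed 3 cell concentrations (100, 200 and 300 cells per µl), 2 numbers of first-round PCR cycles (11 and 13) and 2 shares of the beads taken into reverse transcription (1/3 and 2/3), with 1 library per combination and so 4 libraries per concentration. Within each concentration, replicates 1 and 2 used 1/3 of the beads and replicates 3 and 4 used 2/3. Replicates 1 and 3 had 11 cycles and replicates 2 and 4 had 13. Gene counts per library at 100 cells per µl were 4109482, 6852466, 4248135 and 5699043 for replicates 1 to 4. At 200 cells per µl they were 6534173, 6024878, 5890443 and 5681452, and at 300 cells per µl 6539198, 5107967, 6045195 and 5981355. The labels do not say that libraries came from separate droplet runs or cultures, so p-values measure the spread between these libraries, which may be technical.

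K562 cells outnumbered MEF cells in all 12 libraries. Of 746 deposited barcodes, 470 held at least 90% human counts and were taken as K562, 153 held at least 90% mouse counts and were taken as MEF, and 123 were mixed. K562 barcodes numbered 21.5 ± 4.51 per library at 100 cells per µl, 27.5 ± 4.80 at 200 and 68.5 ± 17.9 at 300 (mean ± SD, n = 4 libraries each). MEF barcodes numbered 3.75 ± 1.5, 11.5 ± 1.29 and 23.0 ± 3.16. The K562 share of single-species barcodes was 85.0% ± 5.38 at 100, 70.3% ± 2.10 at 200 and 74.3% ± 4.94 at 300 cells per µl. Its slope of −5.35 percentage points per 100 cells per µl did not pass an exact two-sided permutation test within matched settings (p = 0.0941, adjusted p = 0.287 over the 15 tests of barcode measures). Over barcodes with at least 2000 detected genes, a minimum chosen after the data were seen, the share at 100 cells per µl was 75.5% ± 8.38 and the slope −0.713 points (exact permutation p = 0.784, adjusted p = 0.871). At a purity of 95% in place of 90% the slope was −0.125 points.

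Mixed-species barcodes made up 32.6% ± 33.2 of barcodes at 100 cells per µl, 8.89% ± 2.42 at 200 and 6.29% ± 1.74 at 300 (SD, n = 4 each). At 100 cells per µl the libraries made with 1/3 of the beads stood apart. Replicate 1 held 48.6% mixed barcodes (95% exact Clopper-Pearson interval 31.9% to 65.6%, 18 of 37). Replicate 2 held 71.6% (61.0% to 80.7%, 63 of 88). Replicates 3 and 4 held 3.23% (0.0816% to 16.7%, 1 of 31) and 6.90% (0.846% to 22.8%, 2 of 29). The slope was −13.1 percentage points per 100 cells per µl (exact permutation p = 0.0957, adjusted p = 0.287). Libraries with 13 cycles differed from those with 11 by 5.06 points (higher in 4 of 6 matched pairs, exact permutation p = 0.188, adjusted p = 0.402). Libraries with 2/3 of the beads differed from those with 1/3 by −19.2 points (lower in 5 of 6 pairs, exact permutation p = 0.125, adjusted p = 0.3125). None of the 3 settings passed. For cycles and bead share the smallest possible p is 0.03125, so most of the 15 tests would have to reach it for an adjusted p under 0.05. Without replicate 2 at 100 cells per µl the slope with concentration was −6.72 points. The difference by bead share was −10.1 points without replicate 2 or 4 at 100 cells per µl, and that by cycles 1.49 points without replicate 1 or 2. Among barcodes with at least 2000 detected genes, mixed shares were 2.17% ± 4.35, 2.35% ± 2.72 and 5.89% ± 1.01 at 100, 200 and 300 cells per µl, and the slope was 1.86 points with the opposite sign (exact permutation p = 0.157, adjusted p = 0.295).

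**Figure D1:**
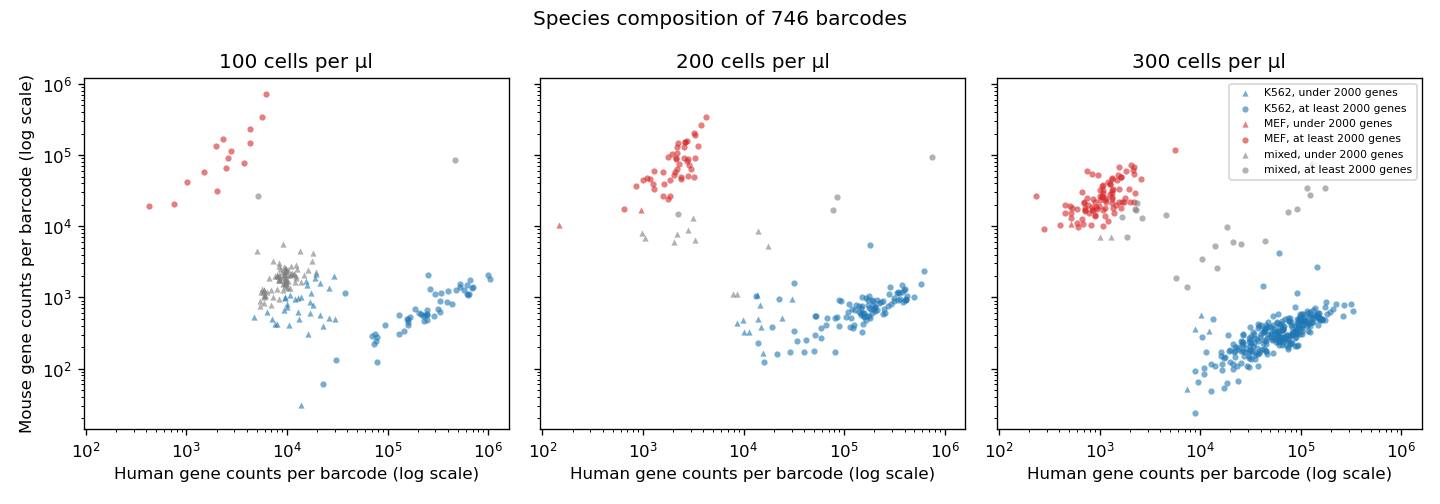
Human against mouse gene counts of each of 746 barcodes (both axes log scale) in the libraries at 100, 200 and 300 cells per µl; blue is K562, red MEF and grey mixed, with triangles for barcodes under 2000 detected genes and circles for the others. At 100 cells per µl most grey points are triangles, and 81 of the 125 barcodes in replicates 1 and 2 were mixed.

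**Figure D2:**
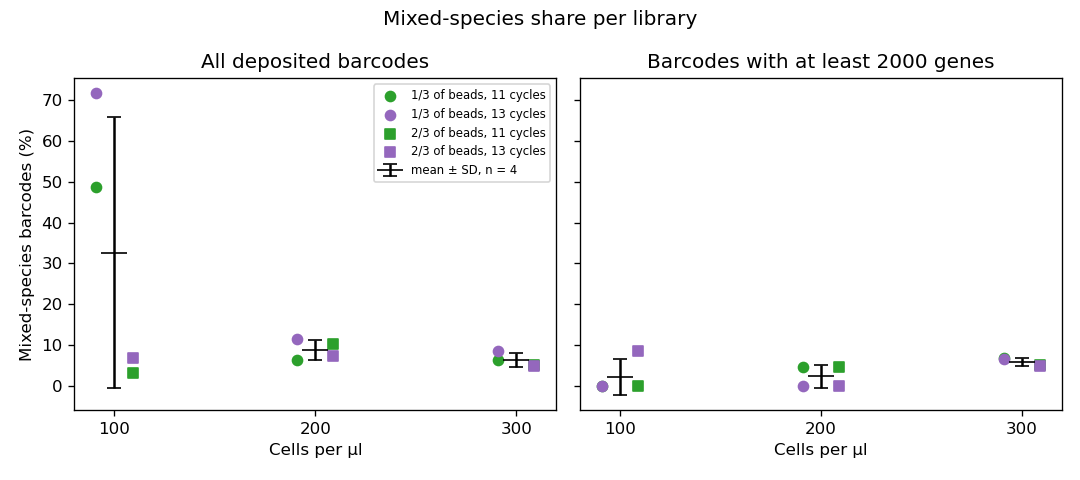
Mixed-species barcodes in percent against cells per µl, 1 point per library, for all deposited barcodes and for barcodes with at least 2000 genes; symbols give the bead share, colours the PCR cycles, and bars the mean ± SD of 4 libraries. The mean at 100 cells per µl is 32.6% over all barcodes and 2.17% over those with at least 2000 genes.

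Numbers of barcodes and counts per cell were compared across concentrations. Libraries held 46.25 ± 28.0 barcodes at 100, 42.75 ± 6.02 at 200 and 97.5 ± 19.8 at 300 cells per µl, a log2 slope of 0.61 per 100 cells per µl (exact permutation p = 0.0340, adjusted p = 0.170). Median counts per K562 barcode were 108952 ± 60572, 157250 ± 27467 and 69540 ± 21450, a log2 slope of −0.17 (exact permutation p = 0.673, adjusted p = 0.776). That slope was −0.60 without replicate 2 and −0.07 without replicate 4 at 100 cells per µl, and −0.05 without replicate 3 and 0.05 without replicate 4 at 300. Counts per MEF barcode were 142693 ± 141168, 72296 ± 23674 and 25728 ± 4782, a log2 slope of −0.99 (exact permutation p = 0.0123, adjusted p = 0.116). None of these passed the adjusted threshold over all deposited barcodes. With barcodes under 2000 genes left out, barcodes per library rose with concentration (17.25 ± 7.85, 36.75 ± 7.41 and 95.75 ± 21.4, log2 slope 1.28, exact permutation p = 0.00154, the smallest the design allows, adjusted p = 0.00772). Counts per K562 cell fell (366627 ± 210400, 177316 ± 34209 and 69725 ± 21477, log2 slope −1.13, exact permutation adjusted p = 0.00772), while counts per MEF cell had the same log2 slope of −0.99 and the same exact permutation p = 0.0123 as over all barcodes. The slope for MEF cells passed (exact permutation adjusted p = 0.0463) because other tests of the 15 had smaller p-values. Library totals over these barcodes changed far less than barcode numbers, with means of 4.86e+06, 5.95e+06 and 5.90e+06 counts at 100, 200 and 300 cells per µl. Counts per cell thus had to fall as barcodes rose, and their slopes are not a separate effect of concentration. Over all deposited barcodes, PCR cycles and bead share passed for neither count measure nor for the number of barcodes (exact permutation adjusted p from 0.417 to 1). Over barcodes with at least 2000 genes, libraries with 2/3 of the beads held more barcodes in 6 of 6 matched pairs (log2 difference 0.61) and fewer counts per K562 cell in 6 of 6 (log2 difference −0.78). Both had an exact permutation p = 0.03125, the smallest the design allows, and an adjusted p = 0.0670, which did not pass. These measures are tied to each other in the same way.

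Counts of the other species within single-species barcodes, at most 10% by the definition of these barcodes, were compared across concentrations. K562 barcodes held 1.80% ± 2.52 mouse counts at 100 cells per µl, 0.424% ± 0.0794 at 200 and 0.484% ± 0.0595 at 300 (per-library medians, SD, n = 4 each), with a slope of −0.661 points (exact permutation p = 0.304, adjusted p = 0.456). This slope was −0.0131 points without replicate 2 at 100 cells per µl and −0.423 without replicate 2 at 300. MEF barcodes held 2.54% ± 0.823, 2.67% ± 0.602 and 4.06% ± 0.301 human counts, a slope of 0.761 points (exact permutation p = 0.0154, adjusted p = 0.116). Over barcodes with at least 2000 genes, mouse counts in K562 barcodes rose with concentration, from 0.262% ± 0.0123 over 0.394% ± 0.0757 to 0.473% ± 0.0637 (exact permutation p = 0.00154, adjusted p = 0.00772), the opposite sign to the slope over all barcodes, and human counts in MEF barcodes rose (slope 0.754 points, exact permutation p = 0.0154 as over all barcodes, adjusted p = 0.0463).

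Among the human genes of the deposited tables, the highest mean in K562 cells was that of MALAT1, a nuclear long non-coding RNA (chromosome 11, 65265233 to 65273939, hg19). It stood at 7013 ± 2271 CPM (counts scaled to a common total) of all human counts (SD, n = 12 libraries). HSP90AB1, a cytosolic chaperone, followed at 5311 ± 522, RPLP1, a ribosomal stalk protein, at 5263 ± 575, NCL, the nucleolar protein nucleolin, at 4802 ± 525, and FTL, the ferritin light chain that stores iron, at 4763 ± 1007. RPL11, GNB2L1, RPS23 and RPS12, whose products belong to the ribosome or bind it, were also among the first 10, from 3764 ± 244 down to 3359 ± 665. In MEF cells Actb, which encodes cytoplasmic actin (chromosome 5, 143664795 to 143668403, mm9), stood at 12617 ± 2753 CPM of all mouse counts and Vim, the mesenchymal intermediate filament vimentin, at 8895 ± 2013. Malat1 was at 6508 ± 2736, S100a6, a calcium-binding protein, at 5701 ± 1310 and Sparc, a collagen-binding matrix glycoprotein, at 4628 ± 1295. Cst3, B2m, Hsp90ab1, Tmsb4x and Lgals1 ranged from 3821 ± 825 down to 3474 ± 704.

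Globin transcripts of embryonic and fetal type were abundant in K562 cells. These genes have no mouse gene of the same symbol, and they are named here after their values were seen. HBG2 (chromosome 11, 5274421 to 5276011, hg19) stood at 2375 ± 589 CPM and HBG1 (5269502 to 5271087) at 1369 ± 440 (SD, n = 12), a fetal pair so alike in sequence that the split of reads between them is uncertain. The embryonic HBZ on chromosome 16 (202854 to 204504) was at 822 ± 500 CPM. HBA1 and HBA2, also near-identical copies, were at 324 ± 193 and 153 ± 141. HBD was at 39.6 ± 12.4 CPM. HBB, the adult beta chain, was at 0.306 ± 0.470 CPM, with 16 counts over all K562 barcodes. The embryonic HBE1 (chromosome 11, 5289580 to 5291373) averaged 883 ± 1459 CPM, but 1 library decided that mean. It was 5353 in replicate 1 at 100 cells per µl, where a single barcode held 99.5% of the 18978 HBE1 counts, and from 62.6 to 1426 in the other libraries.

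The comparison of K562 with MEF used the 16005 gene symbols annotated once in each species, of which 10944 had enough counts to test. Of these, 4412 were higher in K562 and 2756 higher in MEF (edgeR quasi-likelihood test with the library as a block, adjusted p under 0.05; 7492 at an unadjusted p under 0.05). Cell type and species cannot be told apart in this comparison, and human and mouse gene models differ, so a fold here includes both. The median log2 fold change of all tested genes was 0.68 rather than 0, and it shifted by −0.12 with DESeq2, by −0.11 with median-ratio scaling in edgeR and by −0.33 with totals alone. Without the library block it shifted by −0.57, which takes most of the median away, and in thinned sums by 0.08, so changes are to be read against the median of the same fit. The scaling of the main model took as its reference the MEF sum of replicate 1 at 100 cells per µl, which holds 3 barcodes, and leaving out any 1 library shifted the median by −0.10 to −0.24.

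The named genes higher in K562 with the largest folds had no count in any MEF sum, so their folds are lower bounds against 3 counts over all MEF sums. PRAME, a cancer-testis antigen (chromosome 22, 22890123 to 22901696, hg19), stood at 3090 ± 255 CPM of shared-symbol counts in K562 (SD, n = 12) and was at least 9567-fold higher. RHAG, a subunit of the erythrocyte Rh complex, was at 890 ± 85.8 CPM (at least 2756-fold), GATA1, the erythroid transcription factor, at 483 ± 77.7 (at least 1496-fold) and HEMGN, a haematopoietic nuclear protein, at 342 ± 71.3 (at least 1060-fold). SAMSN1 (at least 3119-fold), APOC1 (at least 2037-fold), GTSF1 (at least 1510-fold) and EDARADD (at least 1212-fold) were also of this kind. HIST1H4C and HIST1H2BK, at least 5831-fold and 3751-fold higher, belong to a histone multigene family whose reads may be split between copies and are uncertain. All were higher in K562 in 12 of 12 libraries, which the rule that named them required.

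The genes higher in MEF with the largest folds were of several kinds. COL1A2, a chain of type I collagen, stood at 1836 ± 314 CPM in MEF (SD, n = 12) and was at least 27385-fold higher, TM4SF1, a surface tetraspanin-like protein, at 1882 ± 574 (at least 28068-fold), PENK, the enkephalin precursor, at 1397 ± 965 (at least 20833-fold) and FSTL1, a secreted glycoprotein, at 1233 ± 319 (at least 18385-fold). CKAP4 (at least 15494-fold), CDKN2A, a cell-cycle inhibitor (at least 14748-fold), and PPAP2B (at least 12373-fold) also had no K562 count. MGP, a matrix protein that limits calcification, had 1 count in K562 against 22396 in MEF, a ratio of 106603 (95% counting interval 19133 to 4210600). EMP1 had 2 counts in K562 (ratio 55894, 15473 to 461537), TIMP3, a metalloproteinase inhibitor, 1 count (ratio 75493, 13550 to 2981810) and APP 1 count (ratio 50034, 8980 to 1976230). S100A6 had 17 counts in K562, all in 1 library, and 50752 in MEF. All 12 were higher in MEF in 12 of 12 libraries, which the rule that named them required.

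Red-cell genes were higher in K562. Of 14 measured members of the globin and heme list, 11 were higher in K562, 1 lower and 2 did not pass (12 passed adjusted over the list alone, median log2 fold change 3.17). The globin and heme list had a camera adjusted p = 0.00217, and adjusted p = 0.0653 with an estimated correlation. UROD, an enzyme of heme synthesis, was 45.2-fold higher, BLVRB, which reduces biliverdin and flavins, 7.03-fold, TFRC, the transferrin receptor, 4.47-fold and SLC25A39, a mitochondrial carrier, 3.55-fold. Of 20 erythroid and megakaryocyte regulators, 17 were higher and 1 lower (19 adjusted over the list alone, median 9.51, or 7.49 with the 12 genes without MEF counts at their bounds). The erythroid and megakaryocyte list had a camera adjusted p = 1.27e-07, and adjusted p = 0.0821 with an estimated correlation. GYPC, glycophorin C, was 46.2-fold higher.

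Matrix and cytoskeletal genes were higher in MEF. All 29 extracellular matrix genes were higher in MEF (29 adjusted over the list alone, median log2 fold change −10.95). The extracellular matrix list had a camera adjusted p = 1.71e-21, and adjusted p = 5.11e-06 with an estimated correlation. SPARC was 137-fold higher and SERPINH1, a collagen chaperone, 6.40-fold higher in MEF. Of 22 contractile and actin genes, 18 were higher in MEF and 2 in K562 (20 adjusted over the list alone, median −4.14). The contractile and actin list had a camera adjusted p = 7.83e-10, and adjusted p = 0.0179 with an estimated correlation. ACTB was 4.65-fold, VIM 7.95-fold and TMSB4X, an actin-sequestering peptide, 4.34-fold higher in MEF.

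**Figure D3:**
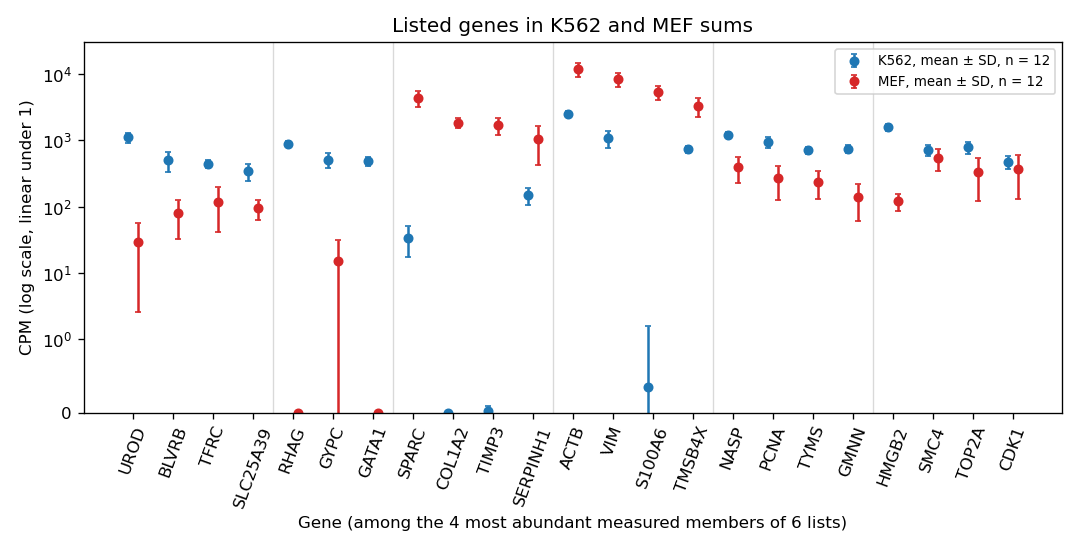
CPM (log scale, linear under 1) of genes among the 4 most abundant measured members of 6 lists (globin and heme, erythroid regulators, extracellular matrix, contractile, S phase, G2/M phase; grey lines part the lists), as mean ± SD of 12 libraries in K562 (blue) and MEF (red). RHAG and GATA1 are at 0 in MEF, and COL1A2 is at 0 in K562; error bars that would pass under 0 end at the axis.

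G2/M genes were mostly higher in K562, while the S phase list did not pass. Of 50 G2/M genes, 38 were higher in K562 and 4 lower (43 adjusted over the list alone, median log2 fold change 1.74). The G2/M list had a camera adjusted p = 0.00217, and adjusted p = 0.348 with an estimated correlation. HMGB2, a chromatin protein, was 13.3-fold higher, TOP2A, which untangles DNA, 2.89-fold and SMC4, a condensin subunit, 1.38-fold. The last lay below the median of all genes and did not pass in 11 of the 12 fits that left out 1 library. CDK1 had a 1.59-fold difference (adjusted p = 0.0913, edgeR). Of 42 S phase genes, 17 were higher and 4 lower (21 adjusted over the list alone, median 0.76, camera adjusted p = 0.0719). NASP, a histone chaperone, was 3.27-fold, PCNA, the DNA polymerase clamp, 3.90-fold, TYMS, thymidylate synthase, 3.27-fold and GMNN, a replication licensing inhibitor, 6.0-fold higher in K562.

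Ribosomal and metabolic lists were mostly higher in K562. Of 76 ribosomal protein genes, 69 were higher and 3 lower (74 adjusted over the list alone, median log2 fold change 4.26). The ribosomal protein list had a camera adjusted p = 1.41e-22, and adjusted p = 0.0444 with an estimated correlation. RPLP1 was 7.34-fold, RPS3 3.01-fold and RPL8 1.76-fold higher. Of 52 nuclear oxidative phosphorylation genes, 43 were higher and 3 lower (46 adjusted over the list alone, median 1.23). The oxidative phosphorylation list had a camera adjusted p = 9.18e-09, and adjusted p = 0.0483 with an estimated correlation. ATP5G3 was 7.18-fold, ATP5J 2.30-fold, ATP5B 2.04-fold and COX4I1 1.33-fold higher, the last below the median of all genes and not past the threshold in 4 of the 12 fits that left out 1 library. Of 21 glycolysis genes, 14 were higher and 3 lower (18 adjusted over the list alone, median 2.24). The glycolysis list had a camera adjusted p = 0.0109, and adjusted p = 0.0821 with an estimated correlation. ENO1 was 12.9-fold and ALDOA 4.74-fold higher. GAPDH had 133670 counts in K562 and 11 in MEF, and LDHB 101214 and 98. GAPDH and many ribosomal protein genes have processed pseudogenes in the mouse genome, so reads of such genes can be shared between copies, and their folds are uncertain. Of 27 proteasome genes, 18 were higher and 2 lower (20 adjusted over the list alone, median 0.75). That median lay close to the median log2 fold change of all tested genes, so much of it is shared with genes outside the list. The proteasome list had a camera adjusted p = 0.00782, and adjusted p = 0.151 with an estimated correlation. PSMA4 was 4.86-fold, PSMA7 2.87-fold, PSMA2 2.84-fold and PSMB1 1.85-fold higher. Of 18 cholesterol synthesis genes, 11 were higher and 1 lower (12 adjusted over the list alone, median 1.55, camera adjusted p = 0.102). FDFT1 was 6.47-fold, FDPS 3.86-fold and SQLE 3.74-fold higher. No member of the mitochondrially encoded list was measured.

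Stress and interferon genes went both ways. Of 22 heat shock and immediate early genes, 14 were higher in K562 and 6 lower (20 adjusted over the list alone, median log2 fold change 1.35). The heat shock list had a camera adjusted p = 0.0483, and adjusted p = 0.299 with an estimated correlation. HSP90AA1 was 9.51-fold, HSPD1, a mitochondrial chaperonin, 9.18-fold and HSP90AB1 1.98-fold higher, and HSPA8, another gene with processed copies, had 120622 counts in K562 and 237 in MEF. Of 20 interferon response genes, 10 were higher in MEF and 2 in K562 (12 adjusted over the list alone, median −1.25). The interferon list had a camera adjusted p = 0.0126, and adjusted p = 0.0821 with an estimated correlation. IFITM3, an antiviral membrane protein, was 35.9-fold higher in MEF while its relative IFITM1 had 34045 counts in K562 and 5 in MEF (760 ± 239 against 0.691 ± 1.93 CPM). B2M, the light chain of class I histocompatibility molecules, was 2.35-fold and BST2 2.42-fold higher in MEF.

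Counts of marker genes of other cell types were also compared. Of 6 macrophage genes, 5 were higher in K562 and 0 lower (5 adjusted over the list alone, median 10.00, or 7.48 with genes at their bounds). The macrophage list had a camera adjusted p = 0.00217, and adjusted p = 0.122 with an estimated correlation. LAPTM5 was at least 627-fold, AIF1 at least 308-fold, CTSS at least 213-fold and PTPRC, the leukocyte surface protein CD45, at least 150-fold higher. Of 4 neural genes, 3 were higher in MEF (4 adjusted over the list alone, median −7.82). The neural list had a camera adjusted p = 0.0173, and adjusted p = 0.0727 with an estimated correlation. NES, an intermediate filament of progenitor cells, was 54.5-fold higher, STMN2 and MAP2 had 3 K562 counts each (ratios 2270 and 1658, intervals 777 to 11005 and 567 to 8038, higher in MEF in 10 and 12 of 12 libraries), and TUBB3 did not pass (adjusted p = 0.0667, edgeR). Of 6 cartilage genes, 5 were higher in MEF and 1 in K562 (6 adjusted over the list alone, median −5.93, or −6.75 with genes at their bounds, since those of HAPLN1 and ACAN, which rest on the mean MEF level, lay beyond the fitted values). The cartilage list had a camera adjusted p = 0.00782, and adjusted p = 0.0483 with an estimated correlation. COL11A1 was at least 1241-fold and SOX9 at least 967-fold higher in MEF, in 11 and 12 of 12 libraries. HAPLN1 stood at 9.94 ± 16.2 CPM in MEF with 124 counts and ACAN at 5.22 ± 9.60 with 54, each higher in MEF in 7 of 12 libraries and without a K562 count. Of 4 endothelial genes, 3 were higher in MEF and 1 in K562 (4 adjusted over the list alone, camera adjusted p = 0.179): FLT1 stood at 32.1 ± 28.4 CPM in MEF and 4.01 ± 11.96 in K562 (higher in MEF in 9 of 12 libraries), ENG had 79 counts in MEF and 4 in K562, the latter in 1 library (higher in MEF in 10 of 12 libraries), and KDR stood at 6.85 ± 8.27 CPM in MEF and had 1 K562 count (higher in MEF in 7 of 12 libraries and in K562 in 1, ratio of mean CPM 307, 55.0 to 12112, against a fitted log2 difference of −5.76). EGFL7 was 9.60-fold higher in K562. Of 7 epithelial genes, 4 were higher in K562 and 3 in MEF (7 adjusted over the list alone, camera adjusted p = 0.482), with KRT18 20.2-fold higher in K562 and KRT19 3.29-fold higher in MEF. EPCAM stood at 258 ± 48.9 CPM in K562 and 1.01 ± 2.79 in MEF, where it had 11 counts, and KRT8 at 209 ± 86.3 and 3.57 ± 9.68, with 45 counts in MEF. Of 6 muscle genes, 3 were higher in K562 and 2 in MEF (5 adjusted over the list alone, median 1.13, or 0.73 with genes at their bounds and −0.24 with DESeq2, camera adjusted p = 0.929). TNNT1 had 12093 counts in K562 and 4 in MEF, DES was 20.2-fold and MYH3 at least 11.5-fold higher in K562 (in 12 and 8 of 12 libraries), and ACTC1 10.4-fold higher in MEF (in 9 of 12 libraries).

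The share of beads taken into reverse transcription went with K562 expression: 33 genes were higher and 72 lower with 2/3 of the beads than with 1/3, of 11440 tested (edgeR, adjusted p under 0.05; 1561 at an unadjusted p under 0.05). MDM4, a p53 regulator (chromosome 1, 204485507 to 204527248, hg19), stood at 147 ± 21.5 CPM with 2/3 of the beads and 72.1 ± 12.2 with 1/3 (SD, n = 6 each; log2 fold change 1.02, SE 0.16, edgeR adjusted p = 0.0126). The nuclear RNA NEAT1 was at 233 ± 36.7 against 137 ± 28.5, and TPT1, a translationally controlled protein, at 2306 ± 271 against 1387 ± 339. TOMM20, LARP4B, HNRNPD, EIF3B, CLPTM1L and SNX27 were also higher, with log2 fold changes from 0.53 to 1.40. FKBP1A, a prolyl isomerase (chromosome 20, 1349621 to 1373816), fell from 280 ± 28.6 to 142 ± 21.4 CPM (log2 fold change −0.98, SE 0.13, edgeR adjusted p = 0.0114), TUBA1B, an alpha-tubulin, from 1617 ± 205 to 1006 ± 188, and the ATP synthase subunits ATP5A1 and ATP5B by 0.57 on the log2 scale each. ILF2, SERF2, PPP1CA, RPL36, EEF1G and POLR2L were lower by log2 fold changes from −1.04 to −0.43.

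**Figure D4:**
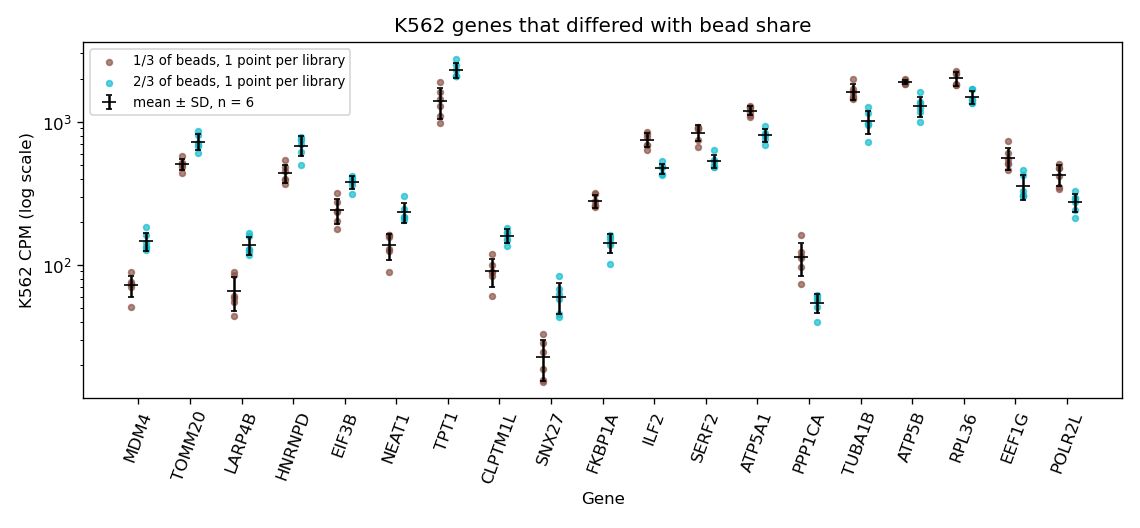
K562 CPM (log scale) of the named genes that differed with bead share, 1 point per library, brown for 1/3 and turquoise for 2/3 of the beads, with mean ± SD of 6 libraries each. FKBP1A averages 142 with 2/3 and 280 with 1/3 of the beads, and MDM4 147 and 72.1.

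Oxidative phosphorylation genes had the smallest camera p of the K562 lists for bead share. Of 53 genes, 4 were lower with 2/3 of the beads and 0 higher (26 adjusted over the list alone, median log2 fold change −0.28, camera adjusted p = 1.82e-24; adjusted p = 0.101 with an estimated correlation; fry adjusted p = 0.00925). Of 76 ribosomal protein genes, 8 were lower and 2 higher (28 adjusted over the list alone, camera adjusted p = 1.32e-07; adjusted p = 0.352 with an estimated correlation). The proteasome, glycolysis, heat shock, interferon and epithelial lists were lower by camera (adjusted p from 4.51e-06 to 0.0142). None held with an estimated correlation in camera (adjusted p = 0.101 for interferon, adjusted p = 0.203 for the others). Across all tested genes, the log2 fold change had a Spearman correlation of 0.306 with exonic length and −0.241 with mean log2 CPM. The list tests were not repeated with these trends removed, so length or abundance as a source of the list results was not tested. The count of genes depended on single libraries: it was 0 without replicate 2, 27 without replicate 1, 11 without replicate 3 and 3 without replicate 4 at 300 cells per µl, 11 and 21 without replicates 3 and 4 at 200, and 15, 8 and 23 without replicates 1, 3 and 4 at 100. DESeq2 called 470 genes, among them all 105, and leaving out both 1/3-bead libraries at 100 cells per µl gave 17.

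PCR cycles and cell concentration gave no K562 gene past the threshold in edgeR (0 of 11440 each; 506 and 637 at an unadjusted p under 0.05; 5 and 7 called by DESeq2). For cycles, the smallest p-values belonged to NHLRC1, a ubiquitin ligase, at 6.26 ± 5.01 CPM with 13 cycles and 0.101 ± 0.171 with 11 (SD, n = 6 each; edgeR adjusted p = 0.884), and to CAPZB, an actin capping protein, at 184 ± 27.2 and 288 ± 46.7 (edgeR adjusted p = 0.884). For concentration they belonged to HSPE1-MOB4, a readthrough locus that overlaps other genes and is uncertain, at 1433 ± 176 CPM at 300 and 889 ± 189 at 100 cells per µl (SD, n = 4 each; edgeR adjusted p = 0.0514), and to RPS27, a ribosomal protein, at 385 ± 72.5 and 207 ± 43.6 (edgeR adjusted p = 0.263). With 13 cycles, camera placed ribosomal proteins (76 genes, 7 adjusted over the list alone, median log2 fold change 0.12, adjusted p = 5.16e-12), oxidative phosphorylation (53 genes, 2 adjusted over the list alone, 0.12, adjusted p = 2.01e-07) and G2/M genes (49 genes, 0 adjusted over the list alone, 0.10, adjusted p = 0.0213) higher and proteasome genes (27 genes, 1 adjusted over the list alone, −0.09, adjusted p = 0.000612) lower. With an estimated correlation none held (adjusted p = 0.640 for ribosomal proteins, oxidative phosphorylation and proteasome, adjusted p = 0.827 for G2/M). With concentration, camera placed globin and heme genes (23 genes, 0 adjusted over the list alone, median −0.21 per 100 cells per µl, adjusted p = 1.10e-06), heat shock genes (22 genes, 3 adjusted over the list alone, −0.07, adjusted p = 0.00263) and cholesterol genes (21 genes, 0 adjusted over the list alone, −0.10, adjusted p = 0.0437) lower. None of the 3 held with an estimated correlation (adjusted p = 0.205 each).

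MEF expression gave no gene past the threshold for any setting in edgeR (0 of 8798; 199 at an unadjusted p under 0.05 for cycles, 385 for bead share and 538 for concentration; DESeq2 called 3, 14 and 4). MEF sums were shallow, from 94196 to 1207193 counts against 3545547 to 5260479 for K562. Serpinh1, the collagen chaperone, stood at 648 ± 187 CPM with 2/3 of the beads and 1598 ± 620 with 1/3 (SD, n = 6 each; edgeR adjusted p = 0.239), and Cd9, a tetraspanin, at 1667 ± 149 and 3560 ± 1238 (edgeR adjusted p = 0.293). Sfrp1, a secreted Wnt antagonist, was at 70.4 ± 49.8 CPM with 13 cycles and 0.837 ± 1.55 with 11, and Usp13, a deubiquitinase, at 1.03 ± 2.13 and 48.8 ± 51.8 (edgeR adjusted p = 1 for both). Sirt4 was at 0.444 ± 0.887 CPM at 300 and 49.8 ± 33.4 at 100 cells per µl, and Tbc1d16 at 21.3 ± 17.9 at 300 with no count at 100 (edgeR adjusted p = 0.807 for both). Camera placed S phase genes lower (42 genes, 0 adjusted over the list alone, median log2 fold change −0.38, adjusted p = 6.58e-08; adjusted p = 0.122 with an estimated correlation) and G2/M (48 genes, 0 adjusted over the list alone, 0.41, adjusted p = 0.00181; adjusted p = 0.889 with an estimated correlation) and glycolysis genes (15 genes, 0 adjusted over the list alone, 0.53, adjusted p = 0.0359; adjusted p = 0.486 with an estimated correlation) higher with 13 cycles. With 2/3 of the beads it placed oxidative phosphorylation (52 genes, 0 adjusted over the list alone, −0.22, adjusted p = 0.0131; adjusted p = 0.488 with an estimated correlation) and G2/M genes lower (−0.15, adjusted p = 0.0481; adjusted p = 0.794 with an estimated correlation), and with concentration G2/M genes higher (0.45 per 100 cells per µl, adjusted p = 0.000112; adjusted p = 0.714 with an estimated correlation).

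Within libraries, the globin and heme score of single K562 cells did not vary with proliferation scores past the threshold. After thinning each cell to 1000 counts, its mean Spearman correlation was −0.0283 ± 0.113 with the S phase score, 0.00406 ± 0.202 with G2/M, 0.106 ± 0.196 with ribosomal proteins and 0.0386 ± 0.182 with heat shock genes (SD, n = 12 libraries, 470 cells). In MEF cells the extracellular matrix score correlated at 0.148 ± 0.224 with S phase, −0.0961 ± 0.264 with G2/M, −0.235 ± 0.367 with contractile genes and −0.124 ± 0.282 with heat shock genes (SD, n = 8 libraries with at least 8 MEF cells, 138 cells). None of the 8 passed (two-sided sign-flip permutation over libraries, smallest adjusted p = 0.354). Scores drawn from 1 total compete for counts, and cells simulated without any covariation gave means from −0.200 to 0.265 for the matrix and contractile pair over 40 draws, with a mean of −0.0252. Of the 40, 0 were at or below the observed −0.235. Leaving out 1 library gave −0.328 to −0.146, and the latter lies within the range of the draws. For the K562 globin and ribosomal pair the draws ranged from −0.164 to 0.0718, with a mean of −0.0387, and 0 of 40 were at or above the observed 0.106. All simulated cells came from 1 pooled profile per cell type at 1 depth, with counting noise only. Real cells can differ in more than counting noise, so 0 of 40 is no support for covariation in either pair.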

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

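Tests chosen after the result was seen are those of RNA from other cells and of paired cells behind mixed barcodes, both tests of the vector region, and for the bead-share genes those of barcodes with few genes and of depth.

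Among the 4 libraries at 100 cells per µl, replicate 2 stood far from the others in its number of barcodes (88 against 29 to 37) and in the mouse share of counts in its K562 barcodes (5.55% against 0.298% to 1.05%; 2 such cases in 62 groups tested, where chance gives about 1 in 20). In replicates 1 and 2, 81 of 125 barcodes were mixed. Mixed barcodes had a median of 506 genes against 6320 in single-species barcodes with at least 2000 genes, a ratio of 0.0801. This cannot decide on paired cells of different species: all 81 mixed barcodes lay under 2000 genes, so the minimum fixed a low ratio. Without the minimum, K562 barcodes had a median of 3258 genes in replicate 1 and 745.5 in replicate 2. For errors of 1 substituted base in the barcodes of deep cells, 0% of barcodes with few genes lay 1 base from a deeper deposited barcode. This cannot decide on such errors, since the rule that chose the deposited barcodes is not given and may have removed or merged such neighbours. Other barcode errors were not compared. RNA from other cells on beads without a cell may account for them: 0% of the 21 barcodes with at least 2000 genes were mixed, which allows up to 14.3% and so does not reach below the 10% set for this test, and barcodes with few genes held 86.2% ± 8.38 human counts in replicate 1 (library 89.2%) and 84.5% ± 6.02 in replicate 2 (library 79.96%). No biological explanation was tested.

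A vector barcode region outside the gene comparisons was counted at 288.3 ± 129 CPM in MEF and 24.2 ± 6.10 CPM in K562 sums (SD, n = 12), 10.7-fold higher in MEF in 12 of 12 libraries (exact sign-flip permutation p = 0.000488, the smallest possible). A few barcodes as the source of the difference are argued against: without the 10% of MEF barcodes with most vector counts (at least 1 per library), which held 24.7% to 60.9% of these counts, the MEF rate was 213 ± 99.5 CPM and still above the K562 rate in 12 of 12 libraries. MEF RNA carried into K562 barcodes as the source of all K562 counts is argued against, since these were 16.6 times the number that the mouse counts would bring (9.34 to 76.5 across libraries). Whether either cell type carried the vector is not given in the sources used here and stays open.

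The change with cell concentration differed between K562 and MEF for 4 of 10944 genes in a test of the difference itself (edgeR; 739 at an unadjusted p under 0.05). The log2 difference per 100 cells per µl was 3.84 for IL1RL1 (adjusted p = 0.000486), 2.88 for COL1A1, 7.18 for CMBL and −7.56 for DCN (adjusted p = 0.0115 each). Each had few counts in 1 cell type, 46, 21 and 70 in K562 for IL1RL1, COL1A1 and DCN and 26 in MEF, in 1 library, for CMBL.

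For K562 genes by bead share, the real split called 105 genes and the highest other 0, in 100 splits drawn, 1 of which was the real one. For K562 against MEF the real split called 7168 genes and the highest other 2641, in 40 splits. Chance is argued against only as far as 1 in 100 and 1 in 40 allow. This also takes the libraries as independent, which the labels do not say. For K562 by cycles (real 0, highest other 0) and concentration (0 and 2), and for MEF by cycles (0 and 0), bead share (0 and 1) and concentration (0 and 1), no gene was called, so all 100 splits necessarily gave as many and decide nothing. For the bead-share genes, gene length as the whole cause is argued against, since 58 of the 105 were still called after the length trend was removed (correlation of fold with length across genes from 0.306 to −0.0115; median absolute log2 fold change from 0.61 to 0.58), although lower genes were shorter (median exonic length 1773) than higher ones (4163). Barcodes with few genes as the source are argued against too, since 95 were still called with at least 2000 genes per barcode. Their removal left the median absolute log2 fold change at 0.61. RNA from other cells on barcodes with at least 2000 genes was not tested. Depth stays open: 102 were still called in thinned sums, but K562 sums hardly differed by bead share (mean log2 difference −0.01), and counts per K562 cell were not equalised. A batch shared by the libraries of 1 bead share could also give such genes, and the labels name none.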

How the results depend on the processing

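The minimums of 2000 genes and 20000 counts and the omission of both 1/3-bead libraries at 100 cells per µl were chosen after seeing the data. K562 against MEF gave a count within 1.5 times its 7168 genes in every alternative run, from 4874 without the block, 4145 of them shared with the 7168, to 7222 with DESeq2, 6507 of them shared. Of the 7168, 14 had the other sign with DESeq2, 11 without the block and 4 without TMM. Named genes reversed in none; 136 of their values lost the threshold and 14 gained it. The cause was not tested in any case below.

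The slope of the K562 share moved from −5.35 to −0.713 points with at least 2000 genes and −0.172 with at least 20000 counts. With at least 2000 genes, slopes reversed for mixed shares by concentration (1.86), cycles (−0.199) and bead share (0.858), for barcodes by cycles (−0.0883) and bead share (0.607), for counts per K562 cell by cycles (0.0978) and bead share (−0.784) and for mouse counts in K562 (0.105), and passed for barcodes (1.28), counts per K562 (−1.13) and MEF cell (−0.991) and human counts in MEF (0.754) by concentration. With at least 20000 counts, barcodes (1.01) and counts per K562 cell (−0.917) by concentration passed, and reversed were barcodes by cycles (−0.0442) and bead share (0.402), counts per K562 cell by cycles (0.0239) and bead share (−0.585) and mouse counts in K562 (0.0856; 0.0903 at 95% purity). Without both 1/3-bead libraries at 100 cells per µl, reversed were barcodes by cycles (−0.0230) and bead share (0.246), counts per K562 cell by bead share (−0.401) and mouse counts in K562 (0.101). Leaving out 1 library gave barcodes by cycles −0.0230 to 0.312 and by bead share −0.263 to 0.146, counts per K562 cell by bead share −0.321 to 0.393 and by concentration −0.600 to 0.0515, and globin with G2/M −0.0290 to 0.0367. Signs turned without replicate 1 or 2 at 100 cells per µl for barcodes by cycles, without replicate 2 or 4 at 100 for both measures by bead share, without replicate 4 at 300 for counts per K562 cell by concentration, and without replicates 2 or 4 at 200 and 3 or 4 at 300 for globin with G2/M.

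K562 genes by bead share numbered 105, and 470 with DESeq2 (all 105 shared), 169 without a filter, 69 without other settings, 17 without both libraries, and 0 to 99 without 1 library. DESeq2 called 5 and 7 K562 genes by cycles and concentration and 3, 14 and 4 MEF genes by cycles, bead share and concentration; without a filter, 2 K562 genes passed by concentration and 15 and 8 MEF genes by bead share and concentration. Lists past camera fell with an estimated correlation from 14 to 5 for K562 against MEF and to 0 for each setting; fry called 2 for K562 by bead share and 0 for the other settings. Globin with heat shock reversed when thinned to 500 counts (−0.0781), unthinned (−0.0555) and with 2000 genes (−0.0107), matrix with heat shock at 500 counts (0.00547) and 2000 genes (0.0356), and matrix with G2/M at 500 counts (0.0702). MEF sums limit what setting effects can be seen.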

Other observations

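The test of shared globin variation was written before its result was seen; the genes were chosen after their levels were.

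Embryonic and fetal globin transcripts varied together across single K562 cells. In 403 cells thinned to 20000 counts, HBZ and HBG2 had a mean within-library Spearman correlation of 0.657 ± 0.156 (SD, n = 12 libraries, above 0 in 12; exact sign-flip permutation adjusted p = 0.00146), HBE1 and HBG2 0.304 ± 0.124 (12 of 12, adjusted p = 0.00146) and HBE1 and HBZ 0.225 ± 0.206 (11 of 12, adjusted p = 0.00879). With HSP90AB1, an abundant chaperone gene taken for comparison, HBE1 correlated at −0.105 ± 0.266 (adjusted p = 0.226), and HBE1 with HBZ lay above it in 10 of 12 libraries. HBE1 counts were concentrated in few cells: the top barcode of each library held 35.5% to 99.5% of them. Cells may differ in a shared globin programme, a hypothesis for which the value of 0.225 could have come out at 0. Other sources of shared variation were not tested.

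The effect of each setting on counts per cell did not differ between K562 and MEF past the threshold (exact permutation adjusted p = 0.234 for concentration and cycles and 0.4375 for bead share).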
